A study of Bos taurus with 3 samples.

How the data were processed

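RNA was measured in 3 libraries of bovine fetal fibroblasts (BFF116), each made from total RNA of 70000 cells, which were starved of serum for 48 h as they would be before nuclear transfer. Per the labels' protocols, thawed cells were lysed, cDNA was made and amplified with a single-primer isothermal method (NuGEN Ovation RNA-Seq version 2), and 500 ng of sonicated cDNA went into each barcoded library, which received 10 PCR cycles. Sequencing on a HiSeq1500 gave single reads of 100 bases at a stated mean of 20000000 reads. Per the submitters' processing notes, bcl2fastq 2.18.0.12, TopHat2 2.0.10 and HTSeq 0.6.1 were used, and the genome build, the annotation, the counting mode and the strand setting are not given in the sources used here.

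The deposited table holds whole-number read counts per gene, not normalized, with 1 column for each of the 3 replicates and 0 columns of other samples. It lists 31903 genes by symbol and 5 summary rows that name no gene, and those rows were kept out of library sizes and tests. Reads in no annotated gene were 59.2, 58.9 and 62.0% of each library's total in replicates 1 to 3, reads with several alignments were 7.93, 7.52 and 7.99%, and reads over more than 1 gene were 0.237, 0.253 and 0.235%. The row for unaligned reads held 0 in every library, so these totals are of counted reads and may not be of all reads sequenced. Gene counts were 8608350, 4842331 and 7122651. Reads with several alignments are missing from the gene counts, so genes with near-identical copies (ribosomal protein genes, EEF1A1, TPT1, ACTB, the histone H3.3 genes, major histocompatibility genes, and the interferon tau and pregnancy-associated glycoprotein families) have uncertain levels. Because the strand setting is not known, reads of a gene and of an overlapping or antisense gene cannot be told apart, as for XIST and for IGF2R with AIRN.

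CPM values, gene counts scaled to the effective library size, were computed from the deposited counts with edgeR 4.0.16 in R 4.3.3 and TMM factors of 0.978, 1.02 and 0.998. Levels on the log2 scale are log2(CPM + 0.5). CPM was not corrected for transcript length, so a comparison of 2 genes or lists also carries their lengths. A count of 3 reads, the limit that 0 reads allows, corresponds to 0.356, 0.605 and 0.422 CPM in replicates 1 to 3. Intervals and this limit cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The limit also does not hold for a gene to which reads could not be assigned, as may be so for GAPDH and BAX at 0 reads. A gene was called measured at 1 CPM or more in every library.

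The series has 1 group, so no comparison between groups was made. Gene lists, list pairs and gene pairs were fixed before the data were examined, and the lists hold 709 genes, of which 643 are in the table. There were 47 lists, covering fibroblast, matrix and contractile genes, markers of other cell types (epithelial, endothelial, leukocyte, erythroid, skeletal muscle, neural, adipocyte, cartilage and bone), pluripotency, trophoblast, hypoblast and oocyte genes, cell cycle and growth arrest, metabolism and stress, senescence, interferon and antigen presentation, chromatin enzymes, imprinted genes, sex chromosomes, HOX and other positional factors, and growth factors. The list of mitochondrial genes had no member in the table and was not analysed here, nor were list members without a row. Each list's median was placed among 10000 random lists of the same size drawn from genes with a read, as a description of these libraries. The fixed lists keep members at 0 reads and the random lists hold none, so low percentiles were not interpreted. List pairs were compared by the difference in mean log2 level with a two-sided permutation of genes between lists (100000 permutations, or all of them where fewer), with Benjamini-Hochberg adjustment over 14 pairs. Genes are not independent replicates. Of 24 planned gene pairs 20 were measured, and the exact sign-flip permutation test for 3 replicates cannot give a p below 0.25. The ratio of summed reads was given with its exact 95% binomial interval where a gene had few reads.

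The spread between replicates was estimated with edgeR on 10434 genes with 10 or more counts in every library, as the common biological coefficient of variation (BCV). Genes more variable than the trend were called from a negative binomial Pearson statistic against chi-square with 2 degrees of freedom at an adjusted p under 0.05. On simulated data for 10434 genes and 3 replicates, this test called 0 unchanged genes, 4 of 100 genes raised 2-fold in 1 replicate and 59 of 100 raised 4-fold, with 0 false calls. The spread of each list was compared with 10000 random lists matched on mean level in 20 bins, and of 100 random lists 8 fell outside the 2.5th to 97.5th percentiles.

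Named genes were the 20 with the highest mean CPM, the 4 highest members of each list, members above or below 1 CPM where these numbered 6 or fewer, both genes of each pair, the most variable genes with a mean of 10 CPM or more (at most 12, of which 2 passed), and every member of the sex chromosome, DNA methylation, histone H3K9 eraser, H3K27 eraser and pluripotency lists, apart from a few genes left out of the text. Other genes are marked as chosen after their values were seen. Alternatives were DESeq2 1.42.0 size factors, plain library sizes, other count filters, dispersions, thresholds and pseudocounts, medians in place of means, and leaving out each replicate. Gene order was taken from a RefSeq table of assembly ARS-UCD2.0, which matched 20250 symbols directly and 616 by a synonym, and was used only for which genes neighbour or overlap each other. Calculations also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.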

Results

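Gene expression was measured by RNA sequencing in BFF116 cells, bovine fetal fibroblasts grown in culture and used as nuclear donors for cloning by somatic cell nuclear transfer. The single group held 3 biological replicates, harvested after 48 h of serum starvation, a step that synchronizes the cell cycle. Reads assigned to genes numbered 8608350, 4842331 and 7122651 in replicates 1 to 3. Of 31903 listed genes, 18039 had a read, 11047 were at 1 CPM or more in every library, and 1381 were at 100 CPM or more. The labels do not say whether the replicates came from separate cultures or animals, so the spread between them may be partly technical. Gene levels are given as mean CPM ± SD of the 3 replicates (n = 3), and genes under 1 CPM in some library as reads in replicates 1 to 3, since their means rest on few reads and can change with 1 library.

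Genes for collagens and other secreted matrix proteins led the profile of these cells. COL3A1 was the most abundant gene at 32239 ± 1761, followed by COL1A2 (26737 ± 2306), COL1A1 (19062 ± 3563), SPARC (17923 ± 1626), which encodes a collagen-binding matrix protein, and THBS1 (15509 ± 778). FN1, the gene of fibronectin, stood at 11556 ± 178, and further matrix genes among the 20 most abundant were DCN (10697 ± 128), COL12A1 (6087 ± 380.2), TNC (4465 ± 708), COL5A2 (4448 ± 526) and LUM (4189 ± 671). The other abundant genes encoded the translation proteins EEF1A1 (14460.5 ± 367) and RPL10 (5637 ± 224), the cytoskeletal proteins VIM (11530.3 ± 413), ACTB (6188 ± 1152), ACTA2 (4029.6 ± 383) and TPM1 (3974 ± 1133), and TPT1 (6881 ± 1393), S100A4 (3841 ± 127) and AHNAK (3818 ± 446). COL1A1 was lower than COL3A1 in all 3 libraries, with a log2 ratio of -0.77 ± 0.26, and lower than COL1A2, with a log2 ratio of -0.50 ± 0.28. The planned exact sign-flip permutation test of 3 replicates cannot give a p below 0.25, so these and the other ratios of 2 genes are described by their direction, mean and SD. The 10 most abundant genes held 16.7% ± 0.747 of gene counts, and the 100 most abundant held 35.9% ± 1.5.

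Whether the donor cultures carried transcripts of other cell types was addressed with fixed marker lists. Fibroblast markers were abundant, with 19 of 20 members at 1 CPM or more in every library. Beside VIM, DCN, LUM and S100A4, these included PDGFRA (2895 ± 222), the receptor of platelet-derived growth factor, and TCF21 was the 1 member below this level, with 1, 0 and 7 reads. The matrix list had 29 of 30 members at this level, and the exception was ELN, the elastin gene, at 11, 2 and 4 reads. Of the contractile genes 12 of 14 were measured, led by ACTA2, TPM1, TPM4 (3739 ± 437) and TPM2 (2583 ± 779), while MYH11 had 41, 2 and 7 reads and MYOCD 0. The medians of these 3 lists stood at the 100th percentile of random lists of the same size.

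Markers of most other cell types were at or near 0 reads. Epithelial genes had 0 of 14 members at 1 CPM in every library, among them KRT19 (1, 9 and 7 reads), KRT8 (3, 8 and 5 reads), CDH1 (5, 4 and 6 reads) and ESRP1 (7, 2 and 5 reads). Erythroid genes had 0 of 9, with AHSP, a haemoglobin chaperone, at 1, 21 and 7 reads, EPB42 (3, 5 and 0 reads) and ALAS2 (0, 1 and 0 reads), and the other 6 members at 0. Skeletal muscle genes had 0 of 11, among them PAX3 (10, 1 and 14 reads), MYF5 (4, 8 and 8 reads), TNNT3 (2, 3 and 5 reads) and MYH3 (0, 3 and 4 reads). Leukocyte genes had 2 of 13, namely CD68 (3.42 ± 1.45) and LYZ (2.77 ± 0.676), and others were FCER1G (26, 1 and 14 reads) and CSF1R (1, 1 and 10 reads). Endothelial genes had 3 of 11, namely ERG (9.67 ± 7.62), TEK (5.93 ± 2.54) and PECAM1 (2.65 ± 1.65), and VWF had 0, 3 and 4 reads. Neural genes had 4 of 12, namely STMN2 (10.6 ± 4.61), MAP2 (5.70 ± 1.28), S100B (4.31 ± 2.97) and TUBB3 (2.91 ± 1.89). Adipocyte genes had 4 of 8, namely LPL (14.3 ± 4.45), FABP4 (6.24 ± 4.11), PLIN1 (3.91 ± 1.76) and PPARG (2.06 ± 1.02), with CIDEC, ADIPOQ, CEBPA and LEP below 1 CPM. Of the cartilage and bone genes 2 of 11 were measured, COL11A1 at 2123 ± 102 and the osteoblast regulator RUNX2 at 206 ± 26.6, and others were SP7 (3, 18 and 5 reads) and ACAN (9, 1 and 3 reads).

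The mean log2 level of fibroblast markers was higher than that of epithelial markers by 8.46 ± 0.10, of endothelial markers by 7.99 ± 0.11, of leukocyte markers by 8.31 ± 0.22, of skeletal muscle markers by 8.47 ± 0.01 and of neural markers by 7.84 ± 0.10. With many members at 0 reads, the sizes depend on the pseudocount, which the SDs over replicates do not cover. The epithelial difference was 9.96 at a pseudocount of 0.1 and 7.73 at 1, and the leukocyte difference 9.92 and 7.58. Each difference had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 2e-05 by permutation of genes between lists. With members restricted to 10 or more counts in every library, the neural difference was 5.86 and no longer passed, and the epithelial, leukocyte and skeletal muscle lists kept fewer than 2 members. In single pairs, CDH2, the cadherin of mesenchymal cells, exceeded the epithelial cadherin CDH1 in every library with a log2 ratio of 7.73 ± 0.06. Because CDH1 had few reads this value depends on the pseudocount, and it was 8.29 at 0.1. The ratio of summed reads of CDH2 over CDH1 was 358 (exact 95% interval 217 to 640). VIM had 236636 reads in all libraries together against 2 reads of the epithelial keratin KRT18, a ratio of 118318 (exact 95% interval 32753 to 976996), which was 70524.5 without replicate 1 and, against a floor of 3 counts per library, at least 18584-fold without replicate 3, where KRT18 had 0. Without replicate 3 ERG stood at 5.37, without replicate 1 PECAM1 at 1.73 and S100B at 2.70, and without replicate 2 TUBB3 at 1.92.

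**Figure D1:**
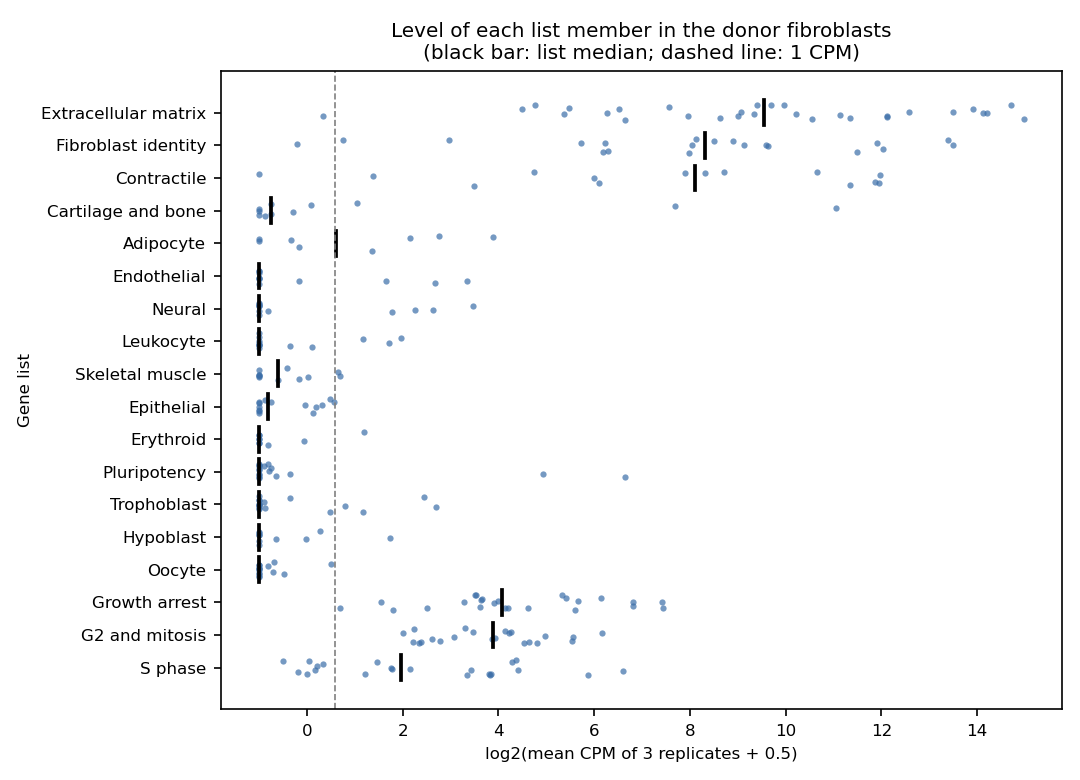
Each point is 1 gene of a fixed list, placed at log2(mean CPM of 3 replicates + 0.5), each black bar is the median of the list, and the dashed line marks 1 CPM. Matrix, fibroblast and contractile lists lie far to the right, and the epithelial, erythroid, oocyte and skeletal muscle lists have 0 members at 1 CPM or more in every library.

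Genes of early embryonic lineages were compared with the donor programme because the nuclei of these cells are meant to be reprogrammed. Of the pluripotency genes 2 of 17 were measured, KLF4 at 99.2 ± 12.8 and MYC at 30.2 ± 11, both transcription factors that are also active in somatic cells. POU5F1, NANOG, SALL4, DPPA2, DPPA3, PRDM14, ESRRB, TFCP2L1 and FGF4 had 0 reads in every library, which allows up to 0.605 CPM in the shallowest. This limit holds only if reads could be assigned to these genes. SOX2 had 0, 0 and 2 reads, LIN28A 0, 0 and 3, LIN28B 1, 0 and 0, ZFP42 0, 1 and 0, DPPA4 2, 0 and 0 and TDGF1 7, 0 and 0. Set against a floor of 3 counts per library for POU5F1, KLF4 was at least 141-fold higher and MYC at least 34.3-fold higher (262 and 77.3 without replicate 2). Both folds require that reads could be assigned to POU5F1. Oocyte genes had 0 of 15 members at 1 CPM in every library, among them NLRP5 (2, 2 and 15 reads), OOEP (2, 0 and 3 reads), DDX4 (3, 0 and 0 reads) and FIGLA (0, 1 and 1 reads). Trophoblast genes had 3 of 17, namely TEAD4 (5.97 ± 2.10), TFAP2A (4.95 ± 4.46) and PAG1 (1.74 ± 0.454), with GATA2 at 10, 4 and 12 reads, and TFAP2A stood at 2.40 without replicate 1. Hypoblast genes had 1 of 10, the exception being RSPO3 (2.80 ± 0.726), and others were GATA6 (2, 3 and 9 reads), TTR (1, 1 and 8 reads) and AFP (0, 0 and 3 reads). The fibroblast list was higher than the pluripotency list by 8.11 ± 0.12 and than the oocyte list by 8.83 ± 0.05 on the log2 scale, each with an adjusted p of 2e-05 by permutation of genes between lists. Both sizes depend on the pseudocount, with 9.91 and 10.8 at 0.1 and 7.33 and 7.96 at 1. The pluripotency difference was 3.10 and no longer passed when only KLF4 and MYC, with 10 or more counts in every library, were kept.

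Growth arrest genes had a higher mean level than S-phase genes over all list members. No unstarved cells were measured, so this difference cannot be tied to starvation. All 24 of 24 arrest genes in the table were measured, led by TXNIP (173 ± 37.0), BTG1 (171 ± 38.5), the cyclin-dependent kinase inhibitor CDKN1A at 113 ± 25.2 and FOXO1 (112 ± 19.4). Of the S-phase genes 15 of 22 were measured, with MCM6 (96.7 ± 17.7), RRM1 (58.2 ± 5.85), POLA1 (20.8 ± 3.95) and TYMS (20.1 ± 6.40) highest. All 22 of 22 genes of G2 and mitosis were measured, led by CENPF (71.6 ± 12.2), TOP2A (46.3 ± 12.8), MKI67 (46.1 ± 9.17) and TPX2 (31.0 ± 7.72). The arrest list exceeded the S-phase list by 2.06 ± 0.26 on the log2 scale (permutation p = 0.001, adjusted p = 0.0017), and the S-phase list was lower than the G2 and mitosis list, with a difference of -1.42 ± 0.16 (permutation p = 0.01, adjusted p = 0.016). The arrest list and the G2 and mitosis list differed by 0.63 ± 0.20, which did not pass (permutation p = 0.18, adjusted p = 0.21), and by 0.92 ± 0.20, which did not pass after adjustment, among members with 10 or more counts in every library. Restricting to members with 10 or more counts in every library, which left 13 of 22 S-phase genes, gave 0.95 and -0.031 for the first 2 differences, and neither passed.

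Single cell cycle genes were compared within libraries. CDKN1A exceeded CDKN1B (42.3 ± 2.05) in every library, with a log2 ratio of 1.38 ± 0.39. PCNA (18.9 ± 6.74) was lower than MKI67 with a log2 ratio of -1.30 ± 0.73, and CCND1 (6.27 ± 0.902) was lower than CCNB1 (10.6 ± 2.56) with a log2 ratio of -0.70 ± 0.29. All 9 of 9 members of the fixed list of G1 cyclins and kinases were measured. The highest was CCNG1 (678 ± 284), which encodes cyclin G1, a name that does not denote the G1 phase. Next came CDK6 (61.5 ± 15.3), CCND2 (50.2 ± 10.3) and CDK4 (48.1 ± 13.1). The list also holds CCNH and CDK7, which are not particular to G1. Immediate early genes, which respond within minutes to serum in quiescent cells, had 18 of 19 members measured. CTGF stood at 2610.4 ± 242, CYR61 at 1443 ± 86.3, EGR1 at 285 ± 92.6 and KLF6 at 177 ± 30.6, while FOSB had 1, 0 and 2 reads.

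Sterol, lysosomal and chaperone genes were abundant. All 19 of 19 genes of cholesterol synthesis were measured, with their median at the 100th percentile, and they included HMGCS1 (852 ± 19.8), SQLE (557 ± 98.8) and CYP51A1 (202 ± 53). Lysosome and autophagy genes had 16 of 18, led by the collagen-degrading protease CTSK at 459 ± 81.5, LAMP2 (299 ± 37.0), CTSB (239 ± 23.8) and MAP1LC3B (200.4 ± 36.0), with CTSL and TFEB below 1 CPM in some library. All 13 of 13 genes of endoplasmic reticulum and amino acid stress were measured, with the chaperones HSP90B1 at 3341 ± 444 and HSPA5 at 3323 ± 192 ahead of ATF4 (714 ± 45.1) and ASNS (455 ± 28.8). All 10 of 10 heat shock genes were measured, led by HSPA8 (1519 ± 56.4), HSP90AB1 (1425 ± 129), HSP90AA1 (1359 ± 165) and HSPD1 (916 ± 119.9). Hypoxia genes had 11 of 13, led by P4HA2 (663 ± 99.0), HIF1A (308 ± 96.7), NDRG1 (264 ± 32.2) and P4HA1 (182 ± 33.1), with CA9 and ANKRD37 below. Glycolysis genes had 13 of 15, led by PKM (598 ± 81.3), LDHB (515 ± 55.4), LDHA (447 ± 55.1) and PGAM1 (309.9 ± 26.3), with HK2 (3, 4 and 12 reads) below. GAPDH was listed at 0 reads in every library, beside expressed neighbours, and its level is uncertain. Apoptosis and DNA damage genes had 12 of 15, among them MCL1 (546 ± 37.0), MDM2 (97.1 ± 55.3) and GADD45A (62.1 ± 14.1), with BAK1 (0, 11 and 4 reads) and BCL2 (4, 18 and 23 reads) below, and BAX was listed at 0 reads within a run of 7 neighbouring genes that had at most 1 read each.

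Of the DNA methylation genes 10 of 13 were at 1 CPM or more in every library, and DNMT3B, DNMT3L and UHRF1 were the exceptions. The de novo methyltransferase DNMT3A (88.4 ± 10.8) exceeded the maintenance methyltransferase DNMT1 (30.5 ± 5.41) in every library, and the log2 ratio of DNMT1 over DNMT3A was -1.53 ± 0.25. DNMT3B had 0, 2 and 9 reads, DNMT3L 0, 0 and 1, and UHRF1, which recruits DNMT1 to replicated DNA, had 5, 6 and 1. The reads of DNMT3A were 162-fold those of DNMT3B over all libraries (exact 95% interval 90.4 to 325), 104-fold without replicate 1 and 551-fold (152 to 4555) without replicate 3. Of the demethylating enzymes, TET2 stood at 105 ± 7.37, TET1 at 86.6 ± 33.2 and TET3 at 72.1 ± 11.7. The log2 ratio of TET3 over TET1 was -0.21 ± 0.29, below 0 in every library, and that of TET2 over TET1, 0.34 ± 0.44, was not of 1 sign. Further members were TDG (42.3 ± 6.09), MBD4 (11.9 ± 4.42), MBD3 (5.68 ± 1.44) and MBD1 (4.69 ± 3.25), and MBD1 stood at 2.82 without replicate 3.

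For lysine 9 of histone H3, the fixed list of methylation erasers had a higher mean level than the list of writers and readers. This covers list members with a row in the table. SUV39H1 and CBX3 of the 10 writer and reader genes listed, and KDM4D and KDM4E of the 9 erasers, had no row. All 7 of 7 eraser genes were measured, KDM1A (213 ± 3.38), KDM3B (125 ± 22.5), KDM3A (122 ± 17.4), KDM4A (79.6 ± 2.30), KDM4C (36.8 ± 5.67), PHF8 (34.1 ± 7.37) and KDM4B (8.23 ± 2.29). All 8 of 8 genes of the writer and reader list were measured, led by CBX5 (49.1 ± 8.14), SETDB1 (31.2 ± 4.68), TRIM28 (24.3 ± 10.4) and SETDB2 (23.6 ± 8.32). The lists are broad, since KDM1A also acts on another lysine of H3, and TRIM28 recruits SETDB1 rather than writing or binding the mark. No difference was computed without these genes. The writer and reader list was lower by a log2 difference of -1.75 ± 0.08 (exact permutation p = 0.022, adjusted p = 0.031). The same members and raw p gave an adjusted value above 0.05 when only 10 list pairs entered the adjustment.

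For lysine 27 of histone H3, writers had 7 of 8 members measured, led by RBBP4 (119 ± 20.5), SUZ12 (47.4 ± 24.0), EZH1 (42.8 ± 4.65) and EED (26.6 ± 6.13), with PHF19 at 7, 11 and 10 reads the exception. Of the erasers 2 of 3 were measured, and KDM6A (84.6 ± 5.47) exceeded KDM6B (7.43 ± 2.96) in every library with a log2 ratio of 3.49 ± 0.54, while the Y-linked UTY had 0 reads. The lists differed by 1.79 ± 0.28, which did not pass (exact permutation p = 0.29, adjusted p = 0.31), and by 0.43 ± 0.46 when members needed 10 or more counts in every library, which dropped UTY and PHF19. EZH2 (19.7 ± 2.69) was lower than EZH1 in every library, with a log2 ratio of -1.11 ± 0.27. Histone acetylation genes had 12 of 15 members measured, led by CREBBP (158 ± 8.48), HDAC1 (141 ± 9.39), HDAC2 (113 ± 66.3) and KAT2B (64.2 ± 23.9), with HDAC4, HDAC11 and KAT2A below. HDAC1 and HDAC2 had no common direction over the libraries, with a log2 ratio of 0.54 ± 1.00. Histone variants and chaperones had 11 of 14 measured, led by H3F3A (819.6 ± 187), NAP1L1 (787 ± 168), H3F3B (457 ± 166) and H2AFZ (223 ± 39.0), with H2AFY2, CHAF1A and ASF1B below.

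Paternally and maternally expressed imprinted genes, whose regulation can be disturbed in cloned embryos, were compared as lists and did not pass the test of a difference. Read counts per gene do not separate the parental alleles, so the comparison does not show whether a gene was imprinted in these cells. Of the paternally expressed genes 9 of 12 were measured, led by PEG10 (486 ± 18.8), SGCE (242 ± 22.9), MEST (180.2 ± 13.9) and PLAGL1 (126 ± 12.4), while DLK1 had 0 reads, RTL1 6, 0 and 1 and AIRN 0, 9 and 0. Of the maternally expressed genes 9 of 12 were measured, led by GNAS (1973 ± 119), IGF2R (114 ± 30.8), UBE3A (91.4 ± 67.5) and H19 (88.0 ± 40.2), with MAOA at 10, 4 and 2 reads and PHLDA2 and SLC22A18 at 0. UBE3A stood at 53.5 without replicate 1. The lists differed by 0.32 ± 0.10, which did not pass (permutation p = 0.83, adjusted p = 0.83), and by 1.02 ± 0.12, which did not pass either, when members needed 10 or more counts in every library. IGF2 (93.2 ± 41.2) and H19, neighbouring genes expressed from opposite parental alleles, had a log2 ratio of 0.11 ± 0.23, and IGF2 over IGF2R had -0.35 ± 0.32, neither with 1 sign in every library.

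XIST, the long noncoding RNA of X inactivation, stood at 1103 ± 404, with 1567, 906 and 835 CPM in replicates 1 to 3. DDX3Y, EIF2S3Y, UTY, ZFY, EIF1AY, SRY, ZRSR2Y, OFD1Y and TSPY had 0 reads in every library, and USP9Y, which has an X-linked copy, had 8, 6 and 10 reads. Against a floor of 3 counts per library for DDX3Y, XIST was at least 1499-fold higher, provided that reads could be assigned to DDX3Y. Insulin-like growth factor genes had 10 of 11 members measured, led by IGFBP4 (255 ± 63.4), IGFBP6 (197 ± 55.3), IGF1R (124 ± 25.5) and IGF2R. IGF1 had 1, 0 and 0 reads, and IGF2 reads were 1861-fold those of IGF1 over all libraries (exact 95% interval 334 to 73545), 899-fold without replicate 3, and at least 151-fold against a floor of 3 counts per library without replicate 1, where IGF1 had 0.

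**Figure D2:**
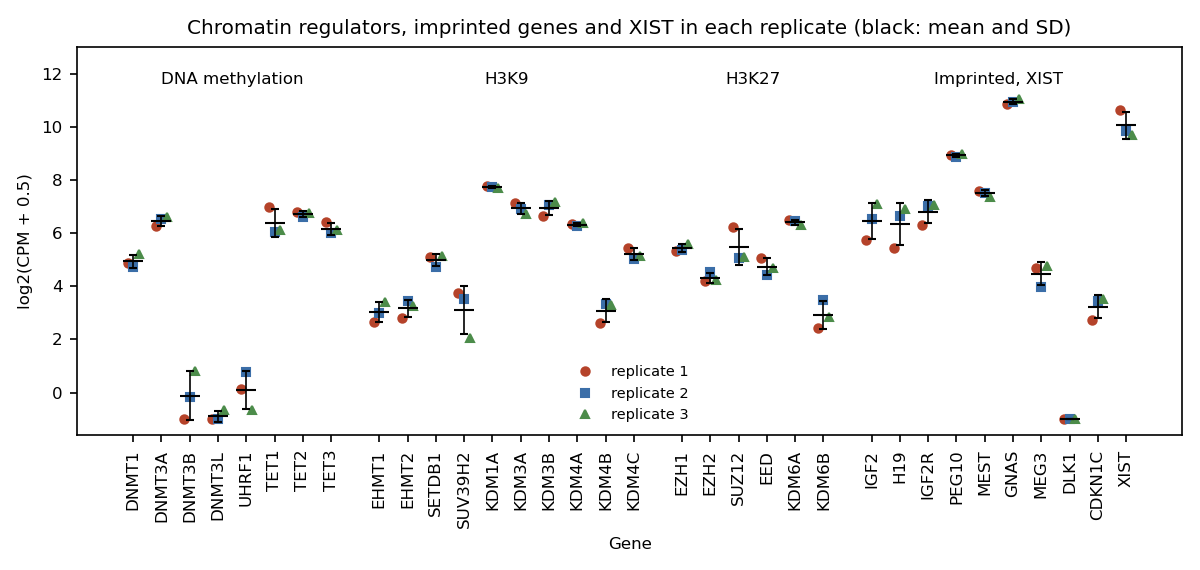
Points give log2(CPM + 0.5) of each gene in replicates 1 to 3, and black marks give the mean and SD over the 3 replicates. DNMT3B, DNMT3L, UHRF1 and DLK1 lie near the bottom, while GNAS (1973 CPM) and XIST (1103 CPM) lie near the top.

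HOX genes, which mark position along the body axis, were measured from anterior to posterior groups. All 7 of 7 central genes were measured, led by HOXC8 (131 ± 16.0), HOXC6 (129 ± 14.1), HOXB6 (31.8 ± 11.2) and HOXD8 (25.6 ± 2.41). Of the anterior genes 10 of 14 were measured, led by HOXC4 (54.5 ± 1.64), HOXB3 (21.2 ± 2.07), HOXA5 (9.33 ± 0.217) and HOXB4 (8.72 ± 3.85), with HOXA2, HOXB1 and HOXD1 among those below 1 CPM in some library. Of the posterior genes 5 of 16 were measured, HOXC10 (26.9 ± 7.81), HOXA9 (11.8 ± 1.27), HOXC9 (5.46 ± 2.86), HOXA10 (4.18 ± 1.47) and HOXB9 (2.57 ± 1.17). The anterior minus posterior difference was 1.38 ± 0.22 and did not pass (permutation p = 0.058, adjusted p = 0.073), and it was -0.060 when members needed 10 or more counts in every library. Of other positional transcription factors 12 of 24 were measured, led by EMX2 (175 ± 13.6), TBX18 (75.9 ± 16.5), MEIS1 (51.6 ± 3.81) and MEIS2 (43.6 ± 3.55).

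Growth factor and receptor genes had 21 of 23 members measured, led by EGFR (172 ± 12.3), FZD1 (159 ± 46.1), PDGFC (138 ± 48.3) and TGFBR2 (101 ± 20.5), with PDGFB at 0 reads and DKK1 at 0, 3 and 0 reads. Senescence-associated genes had 9 of 16, among them GLB1 (159 ± 23.2), IGFBP7 (54.4 ± 14.1) and PLAU (24.2 ± 0.989). Interferon-stimulated genes had 9 of 18, with IFIT1 at 736 ± 245 well above DDX58 (21.2 ± 3.30) and IRF1 (12.6 ± 3.23). Antigen presentation genes had 8 of 12, led by B2M (317 ± 31.1), TAPBP (134 ± 21.1), BOLA-A (27.8 ± 0.538) and JSP.1 (10.2 ± 3.62), with TAP1 at 7, 9 and 0 reads, NLRC5 at 3, 2 and 4 reads and CD74 and CIITA at 0 reads. Over all lists, 15 medians were at or above the 97.5th percentile of random lists.

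CLK1, a kinase of splicing factors, and the uncharacterized gene LOC101909968 differed between replicates by more than genes of like abundance in the test of all 3 replicates, and in none of the tests that left out 1 replicate. CLK1 stood at 157, 47.4 and 30.5 CPM in replicates 1 to 3 and LOC101909968 at 127, 32.0 and 30.0, each with an adjusted p of 0.0106 by the negative binomial test with edgeR's trended dispersion. These 2 were the genes called among 10434, and 547 had an unadjusted p under 0.05 in this test. Of 10434 simulated genes without a change, 4.18% also had an unadjusted p under 0.05, so the 547 were not read as variable genes. Without replicate 1 the test called 6 of 10637 genes, and without replicate 2 or replicate 3 it called 0 of 11041 and 0 of 10665. Genes at an unadjusted p under 0.05 then numbered 472, 419 and 449. The common BCV was 0.273. Replicates 1 and 3 differed most, with an SD of log2 ratios of 0.762 and 1897 of 10434 genes (18.2%) more than 2-fold apart, against 0.614 and 1124 genes (10.8%) for replicates 1 and 2 and 0.525 and 697 genes (6.68%) for replicates 2 and 3.

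The contractile list had the highest spread between replicates of the lists, relative to genes of like abundance, but did not pass an adjustment for the number of lists. The median SD of its members' log2 levels was 0.444 against 0.226 in matched random lists, at the 99.7th percentile, and this was the 1 list of 38 at or above the 97.5th percentile, where chance gives 0.95, with 0 at or below the 2.5th. Its two-sided p from the percentile was 0.0062, with a Benjamini-Hochberg adjusted p of 0.24 over the 38 lists, a test chosen after the percentiles were seen. The list's median log2 level was 7.43, 8.33 and 8.33 in replicates 1 to 3. TPM2 stood at 1826, 2541 and 3383 CPM and TPM1 at 3146, 3509 and 5265, whereas ACTA2 stood at 4024, 3649 and 4416. TAGLN, chosen after its values were seen, stood at 185, 402 and 372. The contractile list stayed between the 97.9th and 99.7th percentiles without any 1 replicate, and the number of lists at or above the 97.5th was 2 without replicate 1 and 3 without replicate 3.

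**Figure D3:**
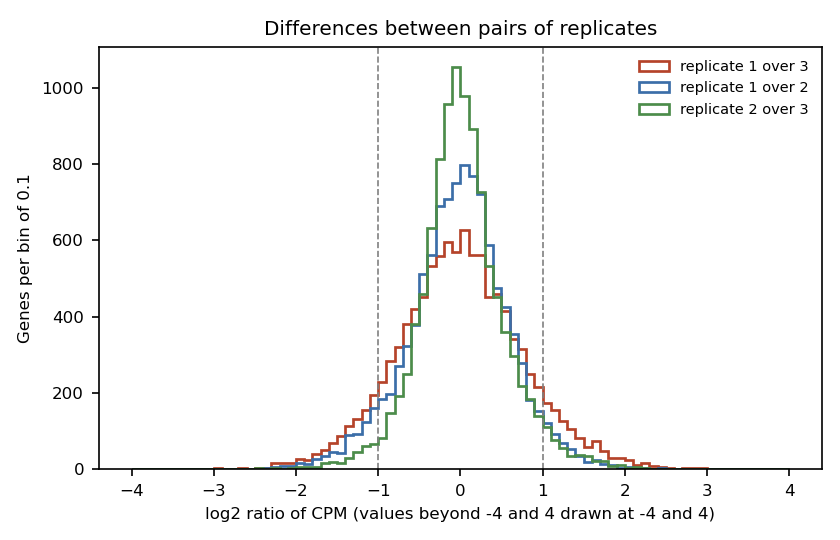
Histograms of the log2 ratio of CPM between each pair of replicates over 10434 genes, in bins of 0.1, with dashed lines at 2-fold differences. The curve of replicate 1 over replicate 3 is the widest (SD 0.762) and that of replicate 2 over replicate 3 the narrowest (SD 0.525).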

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

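Both tests in this part were chosen after the values they measure had been seen. Signals were present in the summary rows of the table, which no comparison above used, and they lay far above the limit that 0 reads allows. Reads assigned to no annotated gene were 60.0% ± 1.71 of the counted reads of each library (SD, n = 3). Reads with several alignments were 7.81% ± 0.256, and reads over more than 1 annotated gene were 0.242% ± 0.00992.

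Most counted reads fell outside the annotated genes in every library. Genomic DNA spread evenly over the genome would put reads into nearly all genes to which reads could be assigned. The 70 markers examined were those of epithelial, endothelial, leukocyte, erythroid, neural and skeletal muscle cells. Of them 39 (55.7%, exact 95% interval 43.3 to 67.6%) had 0 reads in every library, as had 13864 of all 31903 listed genes. This argues against genomic DNA as the whole of the reads outside genes, if reads could be assigned to most of these markers. Mitochondrial or ribosomal RNA cannot be told apart from other sources, because 0 of the listed mitochondrial genes have a row in the table. Reads from introns of unspliced RNA, from unannotated transcript ends, or left out by counting 1 strand only also stay open, untested without a genome and alignments. No biological explanation was tested, since the design has 1 group.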

How the results depend on the processing

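The alternative that set members under 3 counts to 3 counts was chosen after seeing the data, and the others were planned. Measured genes ranged from 8119 to 11987 (11047 as reported), the BCV from 0.199 to 0.337 (0.273 as reported), and the BCV stayed within 1.5 times. The 10 most abundant genes held 18.0% of counts without ribosomal protein genes. Genes more variable than the trend numbered 5 with DESeq2 size factors and 4 with a filter at 100 counts, both holding the 2 reported calls, while common dispersion called 2 others. Leaving out 1 replicate gave 0 to 6 such genes. List pairs that differed numbered 10 under the other alternatives and 1 (fibroblast minus endothelial) when members needed 10 or more counts in every library. Under that filter 4 pairs had too few members, and the differences were 5.86 for fibroblast minus neural, 3.10 for fibroblast minus pluripotency, 0.95 for growth arrest minus S phase, -0.031 for S phase minus G2 and mitosis, and -0.060 for anterior minus posterior HOX genes, which reversed. By construction these rest on fewer members, since those near 0 reads were dropped. The writer minus eraser difference at H3K9 was -1.75 with the same members and raw p, and ended by the adjustment. The other 112 list pair values kept their side and direction, although differences from lists near 0 reads changed in size with the pseudocount. Lists at or above the 97.5th percentile of spread numbered 2 with members of 10 CPM or more and 1 to 3 without 1 replicate, and lists at or below the 2.5th numbered 0 to 2. List level percentiles that moved by more than 1 SD included 41.6 for S phase and 28.3 for interferon genes, both without replicate 2. They also included 83.8 for DNA methylation without replicate 3 and 2.31 for posterior HOX genes without replicate 1. Growth factor genes passed 1 SD by a smaller move, from 99.03 to 99.48 without replicate 3. Genes of endoplasmic reticulum and amino acid stress did so too, from 99.99 to 100 without any 1 replicate. Of gene pair ratios, 7 moved by more than 1 SD, all against genes with few or 0 reads at a pseudocount of 0.1. The mean of 16 listed genes at 1 CPM or more moved by over 1.5 times without 1 replicate, among them SIRT1 and ATRX (40.4 and 127 without replicate 1). Leaving out mitochondrial genes and dividing by exon length were not run, as no such genes or lengths were in the tables used here. No paired analysis was possible because the study had 1 group. At 4842331 gene counts, replicate 2 sets the limit for genes at 0 reads.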

Other observations

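The tests of ambiguous reads and of the stretches around BAX and GAPDH were chosen after the results were seen, the tests of chromosomes and depth followed a look at the uncorrected values, and every gene in the next 2 paragraphs was chosen after its values were seen. Further abundant genes of the donor cells lay outside the fixed lists. Small matrix proteins and matrix-associated growth modulators included FSTL1 (2634 ± 365), ASPN (2446 ± 376), PTN (1257 ± 185), ABI3BP (1144 ± 118) and OGN (1142 ± 572), the last at 1801, 856 and 770.4 CPM in replicates 1 to 3. Genes of the cytoskeleton and the cell surface included TMSB4X (3429.5 ± 274), which encodes an actin-binding peptide, MAP1B (2856 ± 229.8), ANXA2 (2812 ± 151), GJA1 (1621 ± 392), CAV1 (1469.8 ± 88.6) and NOTCH2 (1445 ± 133). Cytoplasmic ribosomal protein genes held 7.57% ± 0.791 of gene counts, and the median of the 73 genes was 810 CPM, while RPS25 stood at 2, 1 and 4 reads.

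Some genes were highest in replicate 1 without passing the adjusted threshold, such as ATRX at 365, 159 and 91.3 CPM in replicates 1 to 3, SENP6 at 399.6, 158 and 98.4, XPO1 at 223, 82.8 and 64.6, SIRT1 at 106, 44.1 and 35.7 and UBE3A at 168, 64.5 and 41.4.

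Replicates 1 and 3 differed across many genes, and the differences ran along chromosomes: the log2 ratio of neighbouring genes had a Pearson r of 0.281 across genes, and of genes 10 places apart 0.179, against at most 0.0367 and 0.0351 in 1000 permutations of gene order each. For replicates 1 and 2 these r were 0.222 and 0.133, and for replicates 2 and 3 they were 0.0611 and 0.0516, so the pattern was strongest in the ratios that involve replicate 1. Whole-chromosome gain or loss is argued against as the whole cause by an r of 0.123 after each chromosome's mean was subtracted. Chromosome medians of the log2 ratio of replicate 1 over 3 ranged from -0.490 to 0.268, so a contribution stays open. Subtracting means does not test parts of chromosomes. Unequal depth is argued against by an SD of log2 ratios that stayed 0.149 above the next pair after thinning to equal reads. Different shares of dividing cells missed their prediction, with percentiles of spread of 84.0 for S phase and 46.4 for G2 and mitosis. Both were under the 97.5 named beforehand. The spread has no direction and the S-phase value was above the middle, so a contribution of dividing cells stays open. A bias tied to a regional property such as base composition may account for the pattern, as a hypothesis, but GC content itself was not tested without a genome, and regional chromatin differences between cultures would give the same correlation. No other biological explanation was tested, since the replicates form 1 group, and genes are not independent replicates.

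GAPDH and BAX, genes used by nearly all cells, were at 0 reads in every library. For BAX a candidate explanation is a stretch of the reference to which reads could not be assigned. In a run of 7 neighbouring genes (BAX, FTL, GYS1, RUVBL2, LHB, NTF4 and KCNA7) each had at most 1 read. The flanking DHDH and SNRNP70 stood at 7.38 and 23.8 CPM. Of the run, LHB, NTF4 and KCNA7 may be silent in fibroblasts, so their 0 reads lend this explanation little weight. A stretch of this kind is argued against for GAPDH, whose neighbours IFFO1 and NCAPD2 stood at 7.55 and 14 CPM. Reads shared with processed copies stay open for GAPDH, because 1.37% of 73 ribosomal protein genes were under 1 CPM, too few genes to set a bound under 5%. Reads set aside as ambiguous are undecided as well. In each library they were at least 68.6 times the reads of the median glycolytic gene. This ratio sets the ambiguous reads of all genes against 1 gene, so it lends the explanation no weight, and these reads are not assigned to genes in the table. The explanation also required another annotated gene overlapping GAPDH and another overlapping BAX, and this was not met for both.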
